A study of Rattus norvegicus with 20 samples.

How the data were processed

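RNA was extracted from rat spinal cord with Trizol and made into libraries with the KAPA RNA HyperPrep kit with RiboErase, per the labels' protocols. This kit removes ribosomal RNA and sequences total RNA. The submitters' processing notes name HISAT2, featureCounts and the genome build rn6, with no versions and no annotation; the strand setting is not given in the sources used here. The authors deposited 1 table per library, with gene symbols and whole-number read counts that were not normalised. The 20 tables each held the same 30452 rows. Of these, 4318 carried a placeholder in place of a symbol. They held 5.87% to 7.37% of the reads and were left out of library totals and tests. Of the 26134 named rows, 5336 had 0 reads in all libraries.

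Groups and replicate numbers were taken from the labels: sham (numbers 1 and 3) and 3 segments at DPI 1, 14 and 28 (numbers 1 and 2, or 1 and 3 at DPI-28). The labels do not say that replicates came from separate animals, so p-values measure the spread between these libraries, which may be technical in part. The segment of the sham cord is not stated in the sources used here. No libraries of a group were identical, and the chi-square statistic per degree of freedom between the libraries of a group ranged from 13.0 to 110. Counts per library in named rows ranged from 1216863 to 5233315. Counting intervals and floors cover counting error only.

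The counts were tested in R 4.3.3 with edgeR 4.0.16: filterByExpr with a minimum count of 10 (12528 rows kept), TMM factors, robust dispersion estimates and the quasi-likelihood F test. All 20 libraries entered 1 model with a term per group and 10 residual degrees of freedom, and 18 contrasts were tested. The common biological coefficient of variation was 0.450. Adjusted p-values are Benjamini-Hochberg values over the tested rows of a comparison, with a threshold of 0.05. CPM values are counts scaled by the TMM-adjusted total in named rows, computed here from the deposited counts. TMM factors were 1.30 to 1.49 in the number-3 libraries and 0.722 to 1.12 in the others. Standard errors are on the log2 scale, from the fold change and its F statistic. For a row with 1 to 3 reads in a group, the ratio of pooled reads is given with an exact 95% interval, and for 0 reads a bound against 3 reads over the group. Gene lists were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and with an estimated one. Principal components used log2(CPM + 1), here scaled by library totals without TMM factors, of the 9016 rows with a mean of at least 5 CPM. The loading and plotting steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

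The steps were tested on simulated counts for epicenter DPI-1 against sham, with known changes in a seeded set of rows. Over 11916 simulated rows that passed the filter, the edgeR test called 0% of the 67 rows changed 2-fold, 8.96% of the 67 changed 4-fold and 57.6% of the 66 changed 8-fold, with 3 false calls among the 11716 unchanged rows. Over 12528 rows DESeq2 called 4.48%, 31.3% and 84.8% of them, with 19 false calls among 12328. At this depth and group size, changes of 4-fold or less were mostly not called by either test in that comparison. In the camera step, over 11965 rows, 1 list of 30 rows above a minimum mean count was raised 2-fold as a whole. This list had a camera adjusted p of 2.69e-10, and 0 of 39 unchanged lists passed. In both simulations rows were drawn independently, with no shift shared by the number-3 libraries. The camera result thus does not give the power or the false calls for the real lists, whose rows can be correlated.

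Symbols were checked against a GRCr8 gene table: 22515 of the names matched a symbol there, and 18743 a protein-coding one. No annotation or genome of rn6 was used here, so the row names could not be set against the positions that were counted, and no coordinates are given. The names of abundant genes used for this check were listed after the data were examined. Each such row's mean count over the 20 libraries was taken as it stands, without normalisation.

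The rows named in the text follow a rule fixed before the data were examined. It takes Pxn, the 6 largest rises and 6 largest falls for the epicenter against sham, and 3 of each for other comparisons. These are taken among rows with an adjusted p under 0.05, at least 10 CPM in the higher group, no overlap between the libraries of the groups, and no provisional identifier. The rule also allowed up to 4 members of each described gene list. These members are not named here, since many names do not go with the counts. Rows named to check the symbols were chosen after their values were seen.

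The design, the comparisons and these alternatives were fixed before the data were examined: DESeq2's size factors in edgeR, library totals alone, no filter on low counts, DESeq2 1.42.0, only the groups compared, each library left out in turn, the replicate number as a block, and an estimated correlation in camera. A term for the number-3 libraries and a fit of only the 16 other libraries were added after seeing the data.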

Results

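Spinal cord of rats was profiled by sequencing of ribosome-depleted total RNA after a contusion injury, which crushes the cord by impact. The 20 libraries fell into 10 groups of 2: sham-operated cord, and the injury epicenter and the rostral (headward) and caudal (tailward) segments at days post injury (DPI) 1, 14 and 28. The series' title names paxillin (Pxn), an adaptor protein of the focal adhesions by which cells attach to their matrix, in endothelial cell migration and the growth of vessels after injury. The 20 count tables held 1216863 to 5233315 reads in named rows. Sham libraries held 3460708 and 1738934 reads, and the shallowest library was epicenter DPI-1 replicate 2.

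Many gene symbols on the rows did not go with the reads in them. Actb, the cytoplasmic beta-actin, had a mean of 0.05 reads per library over all 20 libraries, and Gfap, the intermediate filament of astrocytes, had 0.05. Mbp, myelin basic protein, had a mean of 0.4 reads. The rows Eef2, Hspa8, Aldoa, B2m, Rpl3, Rpl5, Mag and Glul had 0 reads in every library. The 13 rows named after mitochondrially encoded genes also had 0 reads in all libraries. Among 68 names of genes abundant in most tissues or in nervous tissue, 28 (41.18%) had a mean count under 1, and their median count was 3.18 against 6.4 for all 18743 names that match protein-coding genes of GRCr8. The median percentile of the 68 names among these 18743 names was 43.66. Their median stood at percentile 14.31 of 10000 random sets of these names, so it was no higher than that of names drawn at random. Some of these names held many reads: Tpi1 had a mean of 2551 reads, Pkm 882 and Actg1 671, and Cnp, an enzyme of myelin-forming cells, had 238. Among the gene lists checked in the same way, the median percentile was 38.37 for oligodendrocyte and myelin names, 48.79 for oxidative phosphorylation, 49.43 for lysosome and 49.49 for astrocytes. It was 62.12 for neuron and synapse names and 65.69 for hypoxia and glycolysis names, whose median counts stood at percentiles 93.32 and 95.67 of random sets. The rows with the most reads were Dcaf7, with a mean of 3.63% of all reads in named rows, and Dcx, with 2.97%. The names were not without any relation to the counts: 640 of 1202 olfactory and vomeronasal receptor names (53.24%) had a mean count under 1, against 5464 of 17541 other protein-coding names (31.15%; two-sided Fisher's exact test, p = 8.71e-53). Which single rows carry a fitting name was not tested. For this reason a symbol below is used as the label of a row, no gene function is attached to it, and no value below is read as the expression level of the gene whose name the row carries.

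**Figure D1:**
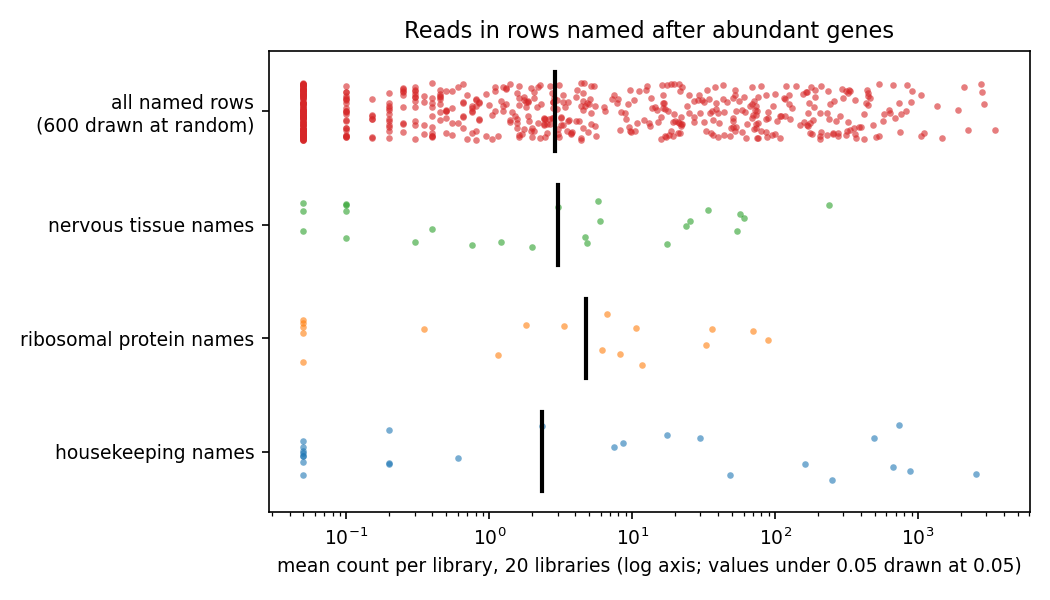
Mean count per library over the 20 libraries (log axis) of rows named after housekeeping genes, ribosomal proteins and nervous tissue genes, and of 600 named rows drawn at random; each point is a row and each black line the median of the whole set. The medians of the 25 housekeeping, 18 ribosomal protein and 25 nervous tissue names were 2.35, 4.75 and 3 reads.

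The 4 libraries whose label carries the number 3 (sham, rostral, epicenter and caudal DPI-28) stood apart from the other 16. On principal component 1, with 47.8% of the variance, they lay between -85.6 and -65.2, and the other libraries between -29.1 and 92.1. Sham replicate 1 lay at -7.95 and sham replicate 3 at -73.2. Libraries of other groups were also far apart on this component: epicenter DPI-1 replicates 1 and 2 lay at 12.2 and 92.1, and caudal DPI-1 replicates 1 and 2 at -2.09 and 91.9. The next highest library after those 2 replicate-2 libraries lay at 45.4. Pearson correlations across rows of the centred values were 0.45 to 0.80 (median 0.673) between number-3 libraries. Between the libraries of 1 group they were -0.197 to 0.62 (median 0.0609). Genes are not independent replicates. The sham and DPI-28 groups each hold a number-1 and a number-3 library, so the same split enters the values within groups. The correlations use the same values as component 1, so they are not separate evidence of the split. The 10 rows with the most reads took 6.36% to 9.76% of the reads in the number-3 libraries and 9.79% to 17.1% in the others. Principal component 2, with 15.8% of the variance, had group means of 50.9 ± 18.2 (SD, n = 2) for epicenter DPI-14 and 24.8 ± 15.1 (SD, n = 2) for epicenter DPI-28. It had -16.3 ± 8.79 (SD, n = 2) for epicenter DPI-1 and -26.1 ± 18.5 (SD, n = 2) for sham. All 6 DPI-14 libraries lay at 9.68 or higher on this component and all 6 DPI-1 libraries at -10.1 or lower, while the 6 DPI-28 libraries ranged from -33.1 to 35.5. These positions were described and not tested.

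**Figure D2:**
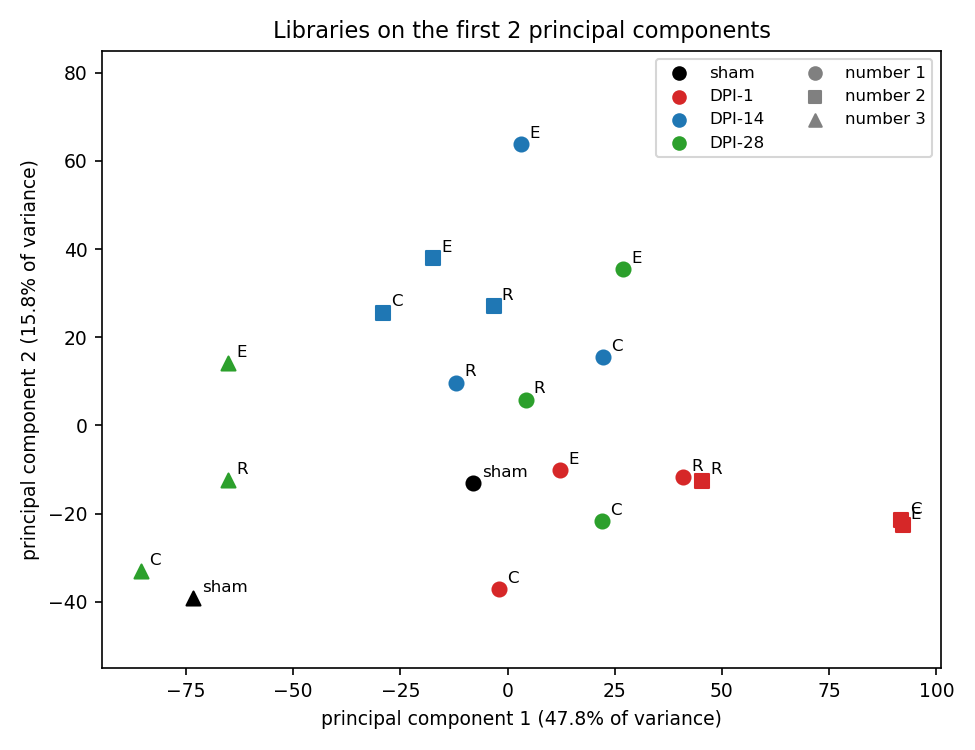
Position of each library on principal components 1 and 2 (log2 CPM, rows with a mean of at least 5 CPM; arbitrary units). Colour gives the day, the marker shape the number in the label, and the letter the segment (R rostral, E epicenter, C caudal); the 4 number-3 libraries lie at -65.2 or lower on component 1.

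The epicenter at DPI-1 was compared with sham to find the rows that differed in the first day of injury. Of 12528 rows tested, 18 passed an adjusted p of 0.05. In the epicenter 12 were higher and 6 lower (10 and 10 when scaled by library totals alone, 156 and 100 by DESeq2). The largest rises were in the rows Chd1 (log2 fold change 3.53), Ceacam1 (3.52), Stk10 (3.10), Snrpe (3.07), Muc5b (3.06) and Tex101 (3.001). Ceacam1 had 278 ± 150 CPM in the epicenter (SD, n = 2) and 24.1 ± 10.4 CPM in sham (SD, n = 2), with a standard error of 0.55 on the log2 scale and an edgeR adjusted p of 0.0326. Stk10 had 166 ± 4.10 CPM (SD, n = 2) against 19.4 ± 3.03 CPM (SD, n = 2), with a standard error of 0.56 and an edgeR adjusted p of 0.0418. The largest falls were in Wfikkn1 (-3.07), Lmbrd2 (-3.04), Errfi1 (-2.70), Heg1 (-2.45), Kank1 (-2.22) and Med20 (-1.95). Heg1 had 17.6 ± 0.574 CPM (SD, n = 2) in the epicenter and 96.0 ± 12.1 CPM (SD, n = 2) in sham (edgeR adjusted p = 0.0326). Every one of the 12 rows had libraries that did not overlap between the groups, which was part of the rule that selected them. With a term for the number-3 libraries in the fit the count was 59 rows, and without those libraries it was 0, with 1 sham library left. The count was 5 without sham replicate 1 and 0 without sham replicate 3, epicenter DPI-1 replicate 1 or epicenter DPI-1 replicate 2.

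The same comparison at DPI-14 called 14 rows, 13 higher and 1 lower in the epicenter (284 and 162 by DESeq2). The row Akna had 393 ± 103 CPM (SD, n = 2) in the epicenter and 4.64 ± 0.939 CPM (SD, n = 2) in sham, a log2 fold change of 6.38 with a standard error of 0.81 (edgeR adjusted p = 0.00865). The row Timp2 had 343 ± 171 CPM (SD, n = 2) against 1.91 ± 1.46 CPM (SD, n = 2), a log2 fold change of 7.37 with a standard error of 1.18 (edgeR adjusted p = 0.0344). Its sham value rests on 10 and 2 reads. Orm1 had 340 reads in the epicenter libraries and 1 in sham, a ratio of 255 (95% counting interval 45.4 to 10093). Slc22a3 had 141 reads against 2, a ratio of 52.8 (95% counting interval 14.4 to 440). Cdc5l, with 3 and 2 reads in the sham libraries, was higher by 4.56 and Tub by 3.19 on the log2 scale. Slc22a3, Cdc5l and Tub lay above both sham libraries in every injured library of all days and segments. Their lowest injured values were 1.39, 3.64 and 9.89 CPM, all in caudal DPI-28 replicate 3. The higher sham values were 0.589, 0.884 and 7.07 CPM. The contrast with sham alone thus does not place these 3 rises at DPI-14 or in the epicenter. The row that fell was Slc4a1, with a log2 fold change of -2.34, from 51.3 ± 14.2 CPM (SD, n = 2) in sham to 10.03 ± 3.60 CPM (SD, n = 2). The count was 49 rows with a term for the number-3 libraries and 1 without them. It was 0 without either sham replicate 1 or sham replicate 3, 1 without epicenter DPI-14 replicate 1 and 9 without epicenter DPI-14 replicate 2.

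At DPI-28 the edgeR test called 3 rows between the epicenter and sham, 3 higher and 0 lower (99 and 49 by DESeq2). Akna had 222 ± 56.5 CPM (SD, n = 2) against 4.64 ± 0.939 CPM (SD, n = 2) in sham, a log2 fold change of 5.56 with a standard error of 0.78 (edgeR adjusted p = 0.0329). Cdc5l had 15.5 ± 0.825 CPM (SD, n = 2) against 0.883 ± 0.000293 CPM in sham (SD, n = 2), a log2 fold change of 4.07 (edgeR adjusted p = 0.0422). The sham libraries held 3 and 2 reads in this row, so the small sham SD does not show a precise baseline. Orm1 had 314 reads against 1, a ratio of 292 (95% counting interval 52.1 to 11575). The count was 84 rows with a term for the number-3 libraries (69 higher, 15 lower), and 0 without them. It was 0 without sham replicate 1, sham replicate 3 or epicenter DPI-28 replicate 1, and 2 without epicenter DPI-28 replicate 3. The 3 comparisons with sham used the same sham libraries, so a row called in several of them is not independent evidence.

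The change over time within the epicenter was taken from DPI-14 against DPI-1, which used no sham library and no number-3 library. It called 24 rows, 20 higher and 4 lower at DPI-14. Akna had 393 ± 103 CPM (SD, n = 2) at DPI-14 and 0.991 ± 1.40 CPM (SD, n = 2) at DPI-1, a log2 fold change of 8.10 with a standard error of 0.93 (edgeR adjusted p = 0.00249). Its DPI-1 value rests on 6 and 0 reads. Metap2 had 291 ± 9.38 CPM (SD, n = 2) against 8.26 ± 4.20 CPM (SD, n = 2), a log2 fold change of 5.04 with a standard error of 0.68 (edgeR adjusted p = 0.0104). Orm1 had 340 reads at DPI-14 and 0 at DPI-1, so that it was at least 59.6-fold higher, computed against 3 reads over the group. The falls named by the rule were Ceacam1 (-3.05), Zbtb2 (-2.22) and Asb2 (-2.20). Ceacam1 went from 278 ± 150 CPM (SD, n = 2) to 33.5 ± 4.12 CPM (SD, n = 2). The spread between replicates was estimated over all 20 libraries. With a term for the number-3 libraries, 492 rows were called (265 higher, 227 lower), and with those libraries left out of the fit 99 were called (67 higher, 32 lower). Leaving out epicenter DPI-1 replicate 1 gave 40 rows and replicate 2 gave 0, and leaving out epicenter DPI-14 replicate 1 gave 2 and replicate 2 gave 5. From DPI-14 to DPI-28 the edgeR test called 0 rows in the epicenter, with 375 at an unadjusted p under 0.05, and DESeq2 called 2. Without epicenter DPI-14 replicate 2 the edgeR test called 2.

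**Figure D3:**
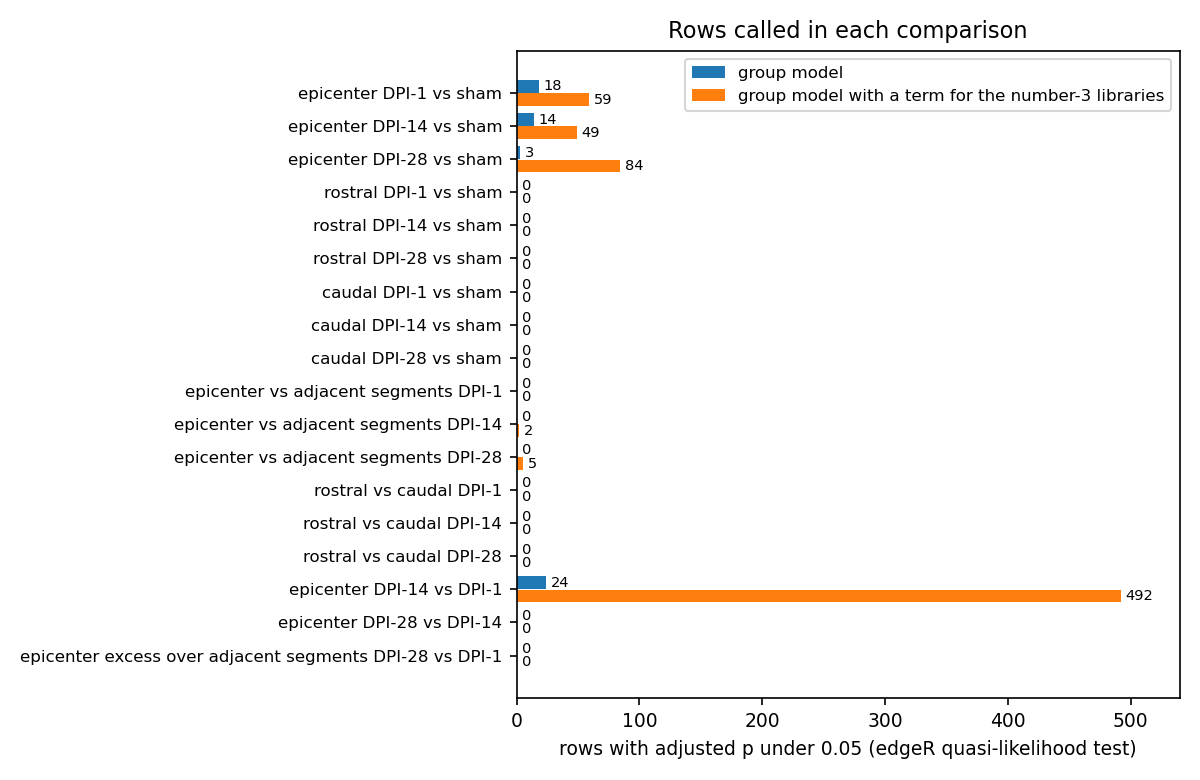
Number of rows with an adjusted p under 0.05 in each of the 18 comparisons (bars from 0), for the model of the 10 groups and for the same model with a term for the 4 number-3 libraries. The counts for the epicenter against sham were 18, 14 and 3 in the first model and 59, 49 and 84 in the second.

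The rostral and caudal segments were each compared with sham at every day, and the edgeR test called 0 rows in all 6 comparisons. At an unadjusted p under 0.05 there were 1166 rows for rostral and 1170 for caudal at DPI-1, 585 and 707 at DPI-14, and 204 and 183 at DPI-28. DESeq2 called 56 and 70 rows at DPI-1, 8 and 17 at DPI-14, and 3 and 1 at DPI-28. Leaving out caudal DPI-1 replicate 1 gave 23 rows for caudal DPI-1 against sham, leaving out sham replicate 1 gave 4 and sham replicate 3 gave 1. The row Akna, called in the epicenter, had 29.8 and 29.7 CPM in the rostral DPI-14 libraries and 31.7 and 77.7 CPM in the caudal ones, against 466 and 320 CPM in the epicenter. At DPI-28 Akna had 74.3 and 33.7 CPM in the rostral and 12.9 and 4.86 CPM in the caudal libraries, and 262 and 182 CPM in the epicenter. The rises named in the epicenter at DPI-1 lay above both sham libraries in every rostral and caudal DPI-1 library. Stk10 had 87.0 and 82.9 CPM rostrally and 77.1 and 86.1 CPM caudally, against 21.5 and 17.2 CPM in sham. The named DPI-1 falls lay below both sham libraries there, except Lmbrd2 rostrally (69.4 and 47.3 CPM against 38.3 and 116 CPM). These rows were selected by their difference from the same sham libraries, which favours such positions. The positions are thus not separate evidence of a change in the adjacent segments, and the share of all tested rows with them was not computed. Among the named rises, only Stk10 and Snrpe lay above both sham libraries in every injured library of all days. The 0 calls do not place these rows in the epicenter alone.

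The direct comparison of the epicenter with the mean of the adjacent segments asked which rows differed by position at a given day. The edgeR test called 0 rows at each day, with 629, 538 and 826 rows at an unadjusted p under 0.05 in the order of the days, and DESeq2 called 7, 10 and 40. With a term for the number-3 libraries the counts were 0, 2 and 5. At DPI-14 the fit of only the groups compared called 12 rows. Leaving out 1 library gave up to 1, 2 and 3 rows, without caudal DPI-1 replicate 1, epicenter DPI-14 replicate 2 and caudal DPI-28 replicate 1. Rostral against caudal gave 0 rows by the edgeR test at each day, with 259, 168 and 151 at an unadjusted p under 0.05, and 0, 0 and 1 by DESeq2. The change of the epicenter's excess over the adjacent segments from DPI-1 to DPI-28 was tested as an interaction, and the edgeR test called 0 rows, with 524 at an unadjusted p under 0.05 and 9 by DESeq2. It gave 2 rows without caudal DPI-1 replicate 1.

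The row labelled Pxn was followed through all groups because the study names paxillin. It had 253 ± 161 CPM in sham (SD, n = 2). In the epicenter it had 362 ± 171 CPM at DPI-1, 114 ± 55.3 CPM at DPI-14 and 90.4 ± 41.8 CPM at DPI-28 (SD, n = 2 each). In the rostral segment it had 395 ± 2.80, 271 ± 55.6 and 186 ± 126 CPM, and in the caudal segment 450 ± 14.1, 248 ± 21.9 and 285 ± 213 CPM, in the order of the days (SD, n = 2 each). Against sham, the log2 fold changes in the epicenter were 0.51 at DPI-1, -1.15 at DPI-14 and -1.48 at DPI-28, with standard errors of 0.62, 0.63 and 0.64. The DPI-1 value turned to -0.0265 with a term for the number-3 libraries and to -0.0103 without those libraries, and that of rostral DPI-14 against sham turned from 0.10 to -0.44 and -0.42. The edgeR adjusted p over all rows was 0.693, 0.443 and 0.494. The row passed in 0 of the 18 comparisons, and the lowest edgeR adjusted p was 0.274, for epicenter DPI-14 against DPI-1 (log2 fold change -1.66, standard error 0.64). That comparison passed with a term for the number-3 libraries (edgeR adjusted p = 0.0208) and with no filter on low counts (edgeR adjusted p = 0.0408). Whether this row holds the reads of the paxillin gene was not tested, and since many row names do not go with the counts, these values are not read as a measurement of paxillin.

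Of 39 gene lists fixed before the data were examined, 38 had at least 5 tested rows, and 0 passed an adjusted p of 0.05 in any of the 18 comparisons by limma's camera test, with a preset or an estimated correlation. The lists nearest to the study's title gave the following counts in the epicenter. Of 35 tested rows named for focal adhesion and cell migration genes, 0 passed over all rows at DPI-14 against sham, and 3 passed when adjusted over the list alone (camera adjusted p = 0.522). Of 18 tested rows named for endothelial cell markers, 0 passed over all rows and 4 when adjusted over the list alone (camera adjusted p = 0.522). Of 15 tested rows named for angiogenesis signalling, 0 passed over all rows and 1 when adjusted over the list alone (camera adjusted p = 0.693). In the same order of lists, 0, 1 and 1 rows passed when adjusted over the list alone at DPI-1, and 0, 1 and 0 at DPI-28. With many row names that do not go with the counts, these tests are not read as results on the pathways or cell types.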

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

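The rows with a placeholder in place of a symbol entered no comparison. They held 7.37% of the reads in caudal DPI-28 replicate 3, above the 6.80% and 6.92% of the sham libraries. Of the 18 injured libraries, 4 lay above the higher sham value: the 3 number-3 libraries of DPI-28 and caudal DPI-14 replicate 2 (7.09%). The other 14 lay below it, with a lowest share of 5.87%. The difference between groups was not tested.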

How the results depend on the processing

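The term for the number-3 libraries and the fit of the other 16 were chosen after seeing the data; the other alternatives were fixed before. Where a count below differs from that in the report the cause was not tested, except that leaving out libraries or groups leaves fewer of them. For the epicenter against sham, in the order of the days, 18, 14 and 3 rows were called in the report. DESeq2's size factors in edgeR moved the count at DPI-28 to 5 and library totals alone moved that at DPI-14 to 25. Library totals alone also moved the median log2 fold change of all rows at DPI-1 from -0.12 to -0.50. Their other counts stayed within 1.5 times, but not all rows were shared with the report. Library totals alone shared 12 of the 18, 10 of the 14 and 1 of the 3 rows for the epicenter against sham. With 21 called, they shared 11 of the 24 for epicenter DPI-14 against DPI-1. With no filter on low counts they were 559, 513 and 194, and 505 for epicenter DPI-14 against DPI-1; the rows called against sham were 355, 365 and 168 higher and 204, 148 and 26 lower. Rostral against sham then gave 421, 137 and 33, caudal 415, 96 and 34, epicenter against adjacent segments 50, 46 and 70, and rostral against caudal 25, 6 and 26. Epicenter DPI-28 against DPI-14 gave 26 and the interaction 77. DESeq2 gave 256, 446 and 148 (156, 284 and 99 higher), with 396 for epicenter DPI-14 against DPI-1, 2 for DPI-28 against DPI-14 and 9 for the interaction. Its counts were 56, 8 and 3 for rostral and 70, 17 and 1 for caudal against sham, 7, 10 and 40 for epicenter against adjacent segments, and 1 for rostral against caudal at DPI-28. On the simulated counts DESeq2 made 19 false calls over 12528 rows and edgeR 3 over the 11916 rows that passed its filter. Those rows were drawn independently with no shift shared by the number-3 libraries, so these counts do not give the error in the real data. Fits of only the groups compared gave 0, 2 and 0, 12 for epicenter against adjacent segments at DPI-14, and 25 for epicenter DPI-14 against DPI-1, 8 of them shared with the report. The term for the number-3 libraries gave 59, 49 and 84, with 492 for epicenter DPI-14 against DPI-1 and 2 and 5 for epicenter against adjacent segments at DPI-14 and DPI-28. Without those libraries the counts were 0, 1 and 0, then 99, 2 and 1. The labels do not say that a number marks an animal, so what libraries of the same number share is not known. Deviations from group means correlated at 0.548 to 0.788 among sham and DPI-28 groups, 0.257 to 0.545 among DPI-1 groups and -0.196 to 0.159 among DPI-14 groups. With the number as a replicate block, epicenter DPI-28 against sham called 84 rows. For the DPI-28 segments against sham this block is the same model as the term for the number-3 libraries, so these 84 rows are not a second result. With the block, epicenter against adjacent segments called 4 at DPI-14 and 2 at DPI-28, and epicenter DPI-14 against DPI-1 called 24. The block moved no other count of calls it could be run for; groups at DPI-1 and DPI-14 share only number 1 with sham.

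Leaving out 1 library at a time leaves a lone library that is assumed to vary like the other groups. It gave 0 to 5, 0 to 9 and 0 to 2 rows for the epicenter against sham in the order of the days, and 0 to 40 for epicenter DPI-14 against DPI-1. It gave 0 to 23 for caudal DPI-1 against sham, 0 to 2 for epicenter DPI-28 against DPI-14 and for the interaction, and 0 to 1, 0 to 2 and 0 to 3 for epicenter against adjacent segments. The gene list tests called 0 to 3 lists, the 3 without sham replicate 1, and 1 list with no filter. For the rows named in the comparisons other than Pxn, 95 values without a single library no longer passed and 17 did, and under the other alternatives 51 no longer passed and 154 did.

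The Pxn row passed in 1 comparison with no filter and in 1 with the term for the number-3 libraries, and its direction turned in several comparisons it did not pass. For rostral DPI-14 against sham, its log2 fold change of 0.10 became -0.00788 with library totals alone, -0.44 with the number-3 term and -0.42 without those libraries. For epicenter DPI-1 against sham, 0.51 became -0.0265 with the term and -0.0103 without the libraries. For epicenter DPI-28 against DPI-14, -0.33 became 0.29 and 0.0304. Without single libraries, the Pxn values against sham ranged from -0.0683 to 1.38 for epicenter DPI-1, from -0.45 to 0.98 for rostral DPI-14, from -1.38 to 0.44 for rostral DPI-28, from -0.57 to 0.85 for caudal DPI-14 and from -0.92 to 1.05 for caudal DPI-28. They ranged from -0.92 to 0.27 for epicenter DPI-28 against DPI-14, from -0.80 to 0.18 for epicenter against adjacent segments at DPI-1, and for rostral against caudal from -0.0926 to 0.33 at DPI-14 and from -1.55 to 0.49 at DPI-28.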

Other observations

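All tests in this part were chosen after the results they bear on were seen, and the patterns are hypotheses found and tested on the same data.

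Many names of abundant genes held few reads, 14 of the 68 with 0 reads in all 20 libraries. No biological explanation was tested, since the pattern spans all groups. Names assigned to rows at random are argued against: 53.24% of receptor names had a mean count under 1 against 31.15% of the others. The medians of chromosomes also ranged over 18.9 reads, and the largest range in 1000 permutations was 12.65. Counting on the opposite strand stays open: 3 of the 20 rows with the most reads overlap another named protein-coding gene in GRCr8, but this leaves out non-coding transcripts and takes the position of the name as the place counted. A candidate explanation is that intervals of one genome build were counted on reads aligned to another, which would keep a name near its region but off its gene; the median percentile of 43.66 for abundant names goes with that, but it cannot be told apart from other displacements without an rn6 annotation.

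Some rows called between groups carried names of neighbouring genes. A row was counted as called if it passed in any of the 18 comparisons, in either direction. Among 46 called rows with a position in GRCr8, 7 pairs lay within 500 kb of each other, against a mean of 1.039 pairs in 10000 random sets of tested rows (one-sided permutation p = 0.0003). The pairs included Orm1 with Akna, Muc5b with Tollip, Lmbrd2 with Il7r, Trim14 with Anp32b, and 3 pairs among Gsk3a, Erf and Ceacam1; those outside the naming rule were chosen after their values were seen. The 7 pairs could come from one transcribed region being read into several neighbouring rows, which displaced intervals could bring about. The count cannot decide this, since the rows of a pair did not have to be called in the same comparison or direction. It also counts 3 pairs from 1 cluster of rows. Neighbouring genes that respond together would give the same count, and this was not tested.

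The number-3 libraries stood apart on principal component 1 by a gap of 36.1 to the nearest other library. Depth is argued against: the gap was 36.2 with all libraries thinned to the same total. Without the 20 rows with the most reads, and with CPM scaled to the rest, the gap was 35.9. The 10 rows with the most reads held at most 17.1% of the reads in any library, and the component used 9016 rows. Leaving out so few rows could move the gap little, so this value does not judge the part played by those rows. The biological grouping by injury is argued against as the whole cause: the sham libraries lay 65.3 apart, while sham replicate 3 lay within 12.3 of each injured number-3 library. One animal behind all 4 libraries is excluded by the labels and not by a distance, since 1 of the 4 is sham and the others are injured. A library batch shared by the number may underlie the split and stays open, because the labels say nothing of what the number marks. The median correlation of 0.673 between these libraries comes from the same values as the component, so it is not separate evidence. Thinned to the same total, number-3 libraries had 13778 to 14807 named rows with a read and the others 11417 to 13936. The fewest were in epicenter and caudal DPI-1 replicate 2 (11417 and 12173), the highest on component 1. Caudal DPI-28 replicate 3, the lowest on it, had the most. What underlies this was not tested.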
